A study of Sclerotinia sclerotiorum with 6 samples.

How the data were processed

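The study measured RNA of Sclerotinia sclerotiorum mycelium by MACE (3′ end sequencing) in 6 libraries, 2 each of AITC, I3C and control. The authors deposited 1 table for the series with raw counts per row and library, per the file headers. Rows are read clusters on scaffolds (13186) or assembled contigs (8510), and 4056 rows join more than 1 locus, up to 100, so that reads of different genes that share a name are summed there. Of all rows, 8544 are described only as uncharacterized RNA. The table holds 6770 distinct locus tags, all of which are found in the RefSeq gene table used here for names. The deposited normalized values are CPM of a group's 2 libraries pooled, as the values show, and were not used for tests. The deposited p-value and adjusted p-value columns are the authors' own, and the submitters' processing notes name DESeq with no version. Aligner, counter, read deduplication and genome build are not given in the sources used here. Counting by names and contigs can split or join paralogs, so multi-locus rows are uncertain as to the gene.

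Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. All 6 libraries entered 1 fit with a mean per group, filterByExpr left 12295 rows, TMM factors ranged from 0.843 to 1.21, and glmQLFit (robust) and glmQLFTest gave p-values, adjusted by Benjamini-Hochberg at 0.05 over the tested rows. The fit had 3 residual degrees of freedom and a common biological coefficient of variation of 0.261. SEs are the log2 change over the root of F, and intervals are at 95%. CPM in the text are normalized with TMM. Gene lists, fixed as text patterns on the row descriptions before the data were examined (28 patterns and 1 list of locus tags), were tested with camera (correlation 0.01), with an estimated correlation, and with fry, adjusted over 84 tests. The pattern for oxalate genes matched 0 row descriptions, so that list was not tested. This does not show that such genes are missing from the table, since many rows carry no described function. fry tests whether a list's genes move one way on balance and does not compare them with other genes.

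Named genes follow a rule set before the data were examined: passed rows whose 2 values in one group lie beyond the 2 of the other, with at least 10 CPM in the higher group and a described function, up to 12 per direction by log2 change, else up to 5 with the smallest p, plus up to 4 members per list and the published tags. Alternatives to the scaling were RLE factors (edgeR's form of the DESeq2 size factors) and library size alone. Other tests were the DESeq2 1.42.0 Wald test and limma-voom. Other filters were no filter and 10 counts in 2 libraries. Further fits used a replicate block or the 4 compared libraries alone, or left out each library in turn. Chosen after seeing the data were scaffold rows alone, single-locus rows alone, thinning every library to the smallest total (1 draw), setting each compound against a different control library, and leaving out rows with under 5% of their CPM (before TMM) in I3C 1, control 1 and control 2 and at least 10 reads.

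The scripts were tested on simulated counts with 200 changed rows among 12295. The changed rows were drawn only from rows above a minimum mean CPM, so the recovery rates do not cover tested rows with fewer reads. For AITC against control, edgeR recovered 16.6% of 2-fold, 88.2% of 4-fold and 98.5% of 8-fold changes, with 9.44% of its calls false, and DESeq2 had 16.3% false. In the simulated I3C against control, where no row was changed, edgeR called 3 rows over 10 simulations and DESeq2 22 over 3. The authors' deposited table has adjusted p under 0.05 for 2317, 678 and 1964 rows in AITC against control, I3C against control and AITC against I3C, and 351, 1 and 341 of the rows called here are among them.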

Results

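Mycelium of the plant-pathogenic fungus Sclerotinia sclerotiorum was grown for 5 days at 24 °C in the dark from agar plugs 2.5 mm across, on plates holding allyl-isothiocyanate (AITC, a mustard-oil compound released from a glucosinolate) at 100 µM, indol-3-carbinol (I3C, a breakdown product of an indole glucosinolate) at 100 µM, or neither compound. RNA was read by MACE, which sequences 1 fragment near the 3′ end of each transcript. Each of the 3 groups held 2 libraries, 6 in all. Nothing in the labels says that the 2 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. The libraries held 6689945 (AITC 1), 15166277 (AITC 2), 6958332 (I3C 1), 13266322 (I3C 2), 12550573 (control 1) and 14959950 (control 2) counts. Libraries of 1 group differed by far more than counting noise, with a chi-square per degree of freedom of 39.0 for AITC, 63.3 for I3C and 92.2 for control, so no pair agreed within counting noise and each was counted as 1 library. This does not tell repeat preparations of 1 RNA from separate cultures. The chi-square was not adjusted for depth, which raises it, so its values do not rank the groups. Of 21696 rows, 12295 were tested. Gene names are those of the best database hit in the deposited table, often from another species, and a row can join several loci that share a name. The number of joined loci is given below for some rows only, so other named rows may join loci too. Positions are on scaffolds as that table numbers them, and its genome build is not given in the sources used here.

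The first comparison asked which transcripts differ in mycelium grown with AITC. Among called rows of at least 10 CPM (normalized read counts scaled by library size), the largest rise was in SS1G_12040, which the table describes as uncharacterized and which is known as an isothiocyanate hydrolase, at 20.8 ± 4.27 CPM (SD, n = 2) with AITC and 0.761 ± 0.407 in control. That is a log2 change of 4.70 ± 0.48 (SE), 26.1-fold, with an edgeR adjusted p of 0.0239, and 42.4-fold without control 2. The row joins 2 loci, the first on scaffold CH476639 from 11640 to 12225. In I3C it stood at 2.04 ± 0.838 CPM, a log2 change of 1.32 against control with a 95% interval of 0.15 to 2.49 and an adjusted p of 0.353. Without control 2 this log2 change was 2.0. The row prpB2 (CH476631, 240552 to 241990), named for a 2-methylisocitrate lyase, an enzyme of propionate breakdown, rose 7.77-fold, from 65.7 ± 11.1 to 510.8 ± 156 CPM. The published tag SS1G_08218 follows it on this scaffold, from 242057 to 242450, and did not rise (log2 -0.37 ± 0.30). Whether the 2 rows belong to 1 gene was not tested, so the role given for prpB2 rests on its best database hit alone. The hexose transporter HXT13 rose 3.71-fold, the sterol methyltransferase erg-4, an enzyme of ergosterol synthesis, 3.41-fold, and the peptidase sed1 3.59-fold. Other rises were in ftmMT (9.48-fold), the glucosidase malL (8.58-fold), the glucanase exgB (7.26-fold), the chitinase CHT1 (6.10-fold), the malate dehydrogenase BcDW1_1717 (4.64-fold), the aspartyl protease SS1G_03629 (3.95-fold), the P450-like ftmP450-3 (3.77-fold, a row joining 21 loci) and SPAC2E11.10 (3.31-fold). The 2 AITC libraries stood apart for ftmMT, at 97.0 and 32.1 CPM, and its fold was 4.73 without AITC 1 and 14.4 without AITC 2. That of CHT1 was 12.2 without control 2.

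The largest fall among rows with a named function was in DDR48, named as a stress protein, at 24.0 ± 3.02 CPM with AITC and 631.0 ± 498 in control, a log2 change of -4.71 ± 0.63 with an edgeR adjusted p of 0.0299. Its control libraries stood far apart, at 983.4 CPM in control 1 and 278.6 in control 2, and it was 11.5-fold lower without control 1 and 41.2-fold without control 2. AIM32 (CH476621, 91035 to 105822) was lower by 13.0-fold, at 985.2 ± 188 CPM against 12776 ± 6711. The glucose-repressible grg-1 was 14.7-fold lower, bli-3 14.6-fold, DR_1172 11.3-fold, the putative magnesium transporter BcDW1_539 10.4-fold, wsp1 6.53-fold, the helicase ECM32 6.11-fold, the glycosyl transferase MBM_00143 5.70-fold, the glucanase-like BcDW1_3766 5.32-fold and the ribosomal L36-like BcDW1_4191 5.26-fold. The oxidoreductase-like BcDW1_5828 was lower by a log2 change of -2.58 ± 0.38. Control 1 stood above control 2 in several of these rows, and without control 1 AIM32 was 8.14-fold lower, grg-1 7.33-fold, bli-3 7.61-fold, DR_1172 6.50-fold, BcDW1_539 5.17-fold, wsp1 4.14-fold and ECM32 3.65-fold. Without control 2, grg-1 was 22.3-fold lower and BcDW1_539 15.7-fold.

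In all, edgeR's quasi-likelihood test called 355 rows, 178 higher and 177 lower with AITC, of which 37 rose and 98 fell by more than 4-fold. All 355 had both AITC libraries on the same side of both control libraries, as had 58.9% of the tested rows, where chance gives 33.3%. Rows vary together, so the spread of this share around 33.3% is not known, and it is no test of a response. For I3C against control, where 1 row was called, the share was 43.6%. The count of 355 moved with single libraries. It was 0 without AITC 1 and 0 without AITC 2 in edgeR (1929 and 2257 rows at an unadjusted p under 0.05), where the lone library is assumed to vary like the other groups, 98 without control 1 (16 higher and 82 lower) and 806 without control 2 (231 higher and 575 lower). It was 1410 with DESeq2 (717 higher and 693 lower), 883 without a filter, 687 with the 4 compared libraries alone (428 higher and 259 lower) and 224 over scaffold rows alone.

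Among the gene lists fixed beforehand, that of DNA replication, repair and cell cycle genes had 138 tested members, of which 14 rose and 2 fell with AITC (36 and 6 when adjusted over the list alone). The median log2 change was 0.36, with a camera adjusted p of 3.16e-05, a fry adjusted p of 0.0312 and an adjusted p of 0.884 with an estimated correlation. The members that rose included the mitotic checkpoint gene mad2 (log2 1.53 ± 0.21), topoisomerase top2 (1.37 ± 0.19), cdc4 (1.49 ± 0.22) and alpha tubulin TUB1 (1.38 ± 0.23), each passing edgeR's adjusted threshold. The list of glycolysis and tricarboxylic acid cycle genes also takes in names with malate synthase or isocitrate lyase. Of its 54 tested members, 3 rose and 0 fell (11 and 0 adjusted over the list alone). Its camera adjusted p was 0.00269, and 0.884 with an estimated correlation. Among those that rose was the malate synthase acu-9 (log2 1.36 ± 0.20). By description prpB2 and BcDW1_1717, both named above, match the pattern too, so the 3 calls do not speak for glycolysis as a whole. The camera call of this list was lost without control 2. Of 46 protease genes, 3 rose and 1 fell (12 and 3 adjusted over the list alone; camera adjusted p = 0.0242, 0.884 with an estimated correlation). This call was lost without AITC 1 and without control 2. Without AITC 1 or AITC 2 edgeR passed no row of the whole table, so no list could have a passing member there. Over all genes no member of these 3 lists passed in edgeR without AITC 1 or without AITC 2, and without control 1 only 1 did, of the glycolysis list. Adjusted over the list alone, the members that rose in the 3 lists in this order were 0, 3 and 3 without AITC 1, 13, 5 and 2 without AITC 2, 14, 10 and 3 without control 1 and 20, 3 and 3 without control 2.

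Cytosolic ribosomal protein genes had a median log2 change of 0.77 and a mean of 1.77 with AITC, with 0 of 106 called up and 1 down over all genes and 51 up and 2 down adjusted over the list alone (camera adjusted p = 4.54e-13, 0.884 with an estimated correlation). The 51 became 0 without AITC 1, without AITC 2 and without control 2, 67 without control 1, 38 without I3C 1 and 33 without I3C 2, and 23 were up over all genes without I3C 1 and 23 without I3C 2. Of these 106 rows, 20 were read almost only in AITC 1, AITC 2 and I3C 2. Those 20 were among 349 such rows in the table, 345 of them contigs, which took 423.7, 432.2 and 452.8 CPM in AITC 1, AITC 2 and I3C 2 and 1.67, 1.99 and 1.82 in I3C 1, control 1 and control 2. Without such rows the list had 0 members up and 1 down adjusted over the list alone, a median of 0.69 and a mean of 0.58, and over scaffold rows alone the mean was 0.50. The oxidative phosphorylation list, with 5 such rows among 67, had 0 members called (median log2 0.38, mean 0.86; camera adjusted p = 0.00291, 0.884 with an estimated correlation), and the oxidoreductase list, with 4 among 62, had 1 up and 1 down (camera adjusted p = 0.0296, 0.891 with an estimated correlation). The oxidoreductase call was lost without these rows and without AITC 1, and both calls were lost without control 2 and over scaffold rows alone. Over all genes each of these 2 lists had 6 members up without I3C 1 and 6 without I3C 2.

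**Figure D1:**
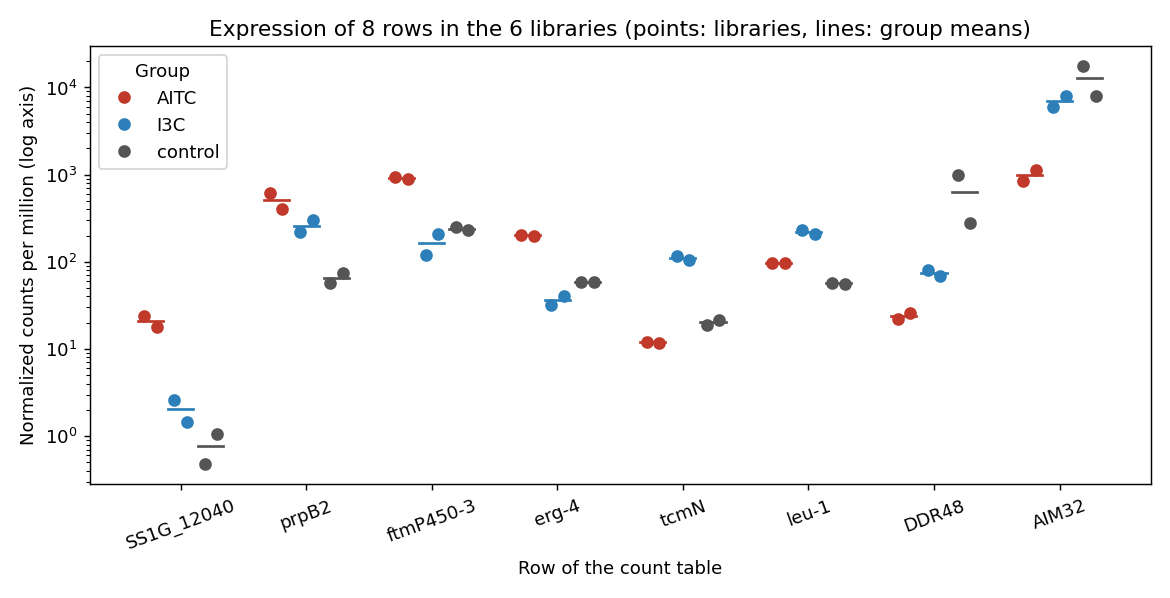
Normalized CPM (log axis) of 8 rows in each library. Points are libraries, lines group means, n = 2 per group. SS1G_12040 averaged 20.8 CPM with AITC and 0.761 in control, tcmN 111.7 with I3C and 20.2 in control, and the 2 control libraries of DDR48 stood at 983.4 and 278.6.

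The second comparison asked the same of I3C. A single row passed edgeR's test: tcmN, named for a bacterial polyketide cyclase and O-methyltransferase (CH476622, 2496322 to 2498197), at 111.7 ± 8.53 CPM with I3C, 20.2 ± 1.95 in control and 11.9 ± 0.266 with AITC, a log2 change of 2.46 ± 0.19 against control with an adjusted p of 0.0258. Its call was lost with the 4 compared libraries alone and without control 1, and its adjusted p ranged from 1.70e-17 to 0.179 over the alternatives. The other rows taken by the naming rule, those with the smallest p in each direction among rows with a named function, did not pass. They were the arylacetonitrilase NECHADRAFT_80653 (5.86-fold higher, adjusted p = 0.0846), the leucine synthesis enzyme leu-1 (3.87-fold higher, 0.0631), prpB2 (3.95-fold higher, 0.147) and the kynurenine monooxygenase kmo (3.25-fold higher, 0.0972) on one side, and plcC, ish1, NST1, fim1 and pgi-1 on the other, with adjusted p of 0.147 to 0.165 in edgeR. Rows of unknown function lay between them in order of p. The I3C and control libraries did not group by treatment in all pairs. Across rows I3C 1 had r = 0.972 with control 2 and 0.963 with I3C 2, and a chi-square per degree of freedom of 53.1 against 63.3. I3C 2 had r = 0.967 with control 2 and also 0.967 with AITC 2, both above its r with I3C 1. Control 2 had its highest r with control 1. Its chi-square per degree of freedom with control 1 was 92.2, above that with I3C 1. Control 1 held more counts than I3C 1, which raises this value, so the 2 values cannot be compared directly. At an unadjusted p under 0.05 there were 1635 rows, 714 higher and 921 lower. Of the I3C libraries only I3C 2 holds the rows read almost only in AITC 1, AITC 2 and I3C 2 (452.8 CPM, against 1.67 in I3C 1). A count made without I3C 1 can therefore include such rows, and how many it includes was not tested. The adjusted count was 319 with DESeq2 (82 higher and 237 lower), 1 with limma-voom and 137 without a filter. It was 65 without I3C 1 (62 higher and 3 lower), 16 without I3C 2 (15 higher and 1 lower), 0 without control 1 in edgeR (937 at an unadjusted p under 0.05) and 225 without control 2 (22 higher and 203 lower).

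Of the lists, heat shock proteins and chaperones (65 tested, 51 lower, median log2 -0.35), ribosome assembly and translation factors (151 tested, 126 lower, median -0.28), antioxidant enzymes (32 tested, 25 lower), cell wall genes (73 tested, 52 lower) and sterol synthesis genes (33 tested, 25 lower) had camera adjusted p of 3.59e-05, 1.30e-06, 0.00904, 0.00534 and 0.0293. No member of any of these passed, over all genes or adjusted over the list alone, though without control 2 there were 2, 1, 4, 2 and 1 lower over all genes, and with an estimated correlation each adjusted p was 0.884. Values of the leading members were log2 -1.55 ± 0.34 for the hsp90-like BcDW1_3165, -1.37 ± 0.33 for hsp88 and -1.04 ± 0.24 for the thioredoxin reductase cys-9. The antioxidant call was lost without control 1, that of the cell wall genes without I3C 1, and that of sterol synthesis without I3C 2 and without control 2. Cytosolic ribosomal proteins were lower in 79 of 106, with a median of -0.55 and a mean of the opposite sign, 0.59, and 20 of them were the rows read almost only in AITC 1, AITC 2 and I3C 2 (camera adjusted p = 1.72e-06, 0.891 with an estimated correlation; lost without I3C 1, where 20 were higher and 1 lower adjusted over the list alone). Without those 20 rows the mean was -0.50, and over scaffold rows alone it was -0.51. The mean was -0.59 without I3C 2 and 1.07 without I3C 1. With library size as the only scaling, the median of all genes stood at 0.39, and these medians are relative to a median of 0.01.

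The third comparison set the compounds against each other at the same dose and time. tcmN was 9.41-fold lower with AITC than with I3C (adjusted p = 0.00512 in edgeR), and NECHADRAFT_80653 4.15-fold lower. The leucine pathway enzyme leu2 was 3.60-fold lower, aps1 4.16-fold, AIM32 7.10-fold, NRPS4 5.31-fold (9 loci joined), NCU04071 4.76-fold, BcDW1_5445 4.66-fold, AN5440 3.90-fold, the sulfate assimilation enzyme sA 3.87-fold, SS1G_11930 3.62-fold and the annexin SS1G_06532 3.13-fold. Higher with AITC were SS1G_12040 (log2 3.38 ± 0.44, adjusted p = 0.0322 in edgeR), ftmMT (13.0-fold), malL (7.45-fold), ccsA (5.84-fold, 21 loci joined), erg-4 (5.52-fold), ftmP450-3 (5.52-fold), CHT1 (5.47-fold), the phospholipase plcC (4.65-fold), HXT13 (4.43-fold), SPCC970.02 (4.10-fold), exgB (4.08-fold), CHGG_05463 (4.02-fold) and the polyketide synthase wA (3.95-fold, 17 loci joined). The fold of ftmMT was 6.61 without AITC 1 and 19.9 without AITC 2, and without I3C 2 that of malL was 13.4 and that of plcC 7.33. In total 345 rows were called, 248 higher and 97 lower with AITC. With library size as the only scaling, 206 were called, 49 higher and 157 lower, and the median of all genes stood at -0.34. The count was 1164 with DESeq2, 813 without a filter, 539 with the 4 compared libraries alone, 0 without AITC 1 and 0 without AITC 2 in edgeR (1729 and 2114 at an unadjusted p under 0.05), 18 without I3C 1 (4 higher and 14 lower) and 372 without I3C 2.

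Cytosolic ribosomal protein genes had the smallest camera p. Of 106 members 33 were higher with AITC and 0 lower (58 and 2 adjusted over the list alone), with a median log2 difference of 1.39 (camera adjusted p = 1.83e-23, 0.884 with an estimated correlation). Examples are rps11a (log2 1.65 ± 0.27), rps4a (1.69 ± 0.28) and rpl-38 (1.69 ± 0.28). Without the rows read almost only in AITC 1, AITC 2 and I3C 2, 44 of 86 were higher, and with library size as the only scaling 4 of 106 were higher and 1 lower. Over all genes no member passed in edgeR without AITC 1, without AITC 2 or without I3C 1 (48, 54 and 47 higher adjusted over the list alone), and 1 did without I3C 2. Of 33 sterol synthesis genes 4 were higher and 0 lower (9 and 1 adjusted over the list alone), led by erg-4 (log2 2.47 ± 0.20) and the lanosterol demethylase CYP51 (1.60 ± 0.19). Its camera adjusted p was 0.00296, fry gave 0.0312, and with an estimated correlation the adjusted p was 0.884. Of 46 protease genes 5 were higher and 0 lower, and of 118 proteasome and ubiquitin genes 7 and 0. The latter included the proteasome subunits pre8 (1.08 ± 0.19) and pre10 (1.05 ± 0.18). Of 54 genes matched by the glycolysis and tricarboxylic acid cycle pattern 4 were higher and 1 lower. With an estimated correlation the adjusted p of the protease, proteasome and glycolysis lists was 0.884, 0.891 and 0.884. Over all genes no member of these 4 lists passed in edgeR without AITC 1, without AITC 2 or without I3C 1, except 1 sterol synthesis gene without I3C 1, and no proteasome and ubiquitin gene did without I3C 2. Without AITC 1 or AITC 2 no row of the whole table passed, so the lack of passing members there is not particular to the ribosomal or any other list. The camera calls of 11 lists in this comparison, all higher with AITC, were each lost with an estimated correlation, where the smallest adjusted p was 0.884. Those of the oxidoreductase, heat shock and ribosome assembly lists were lost without I3C 1, that of heat shock also without AITC 2 and that of ribosome assembly also without AITC 1.

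**Figure D2:**
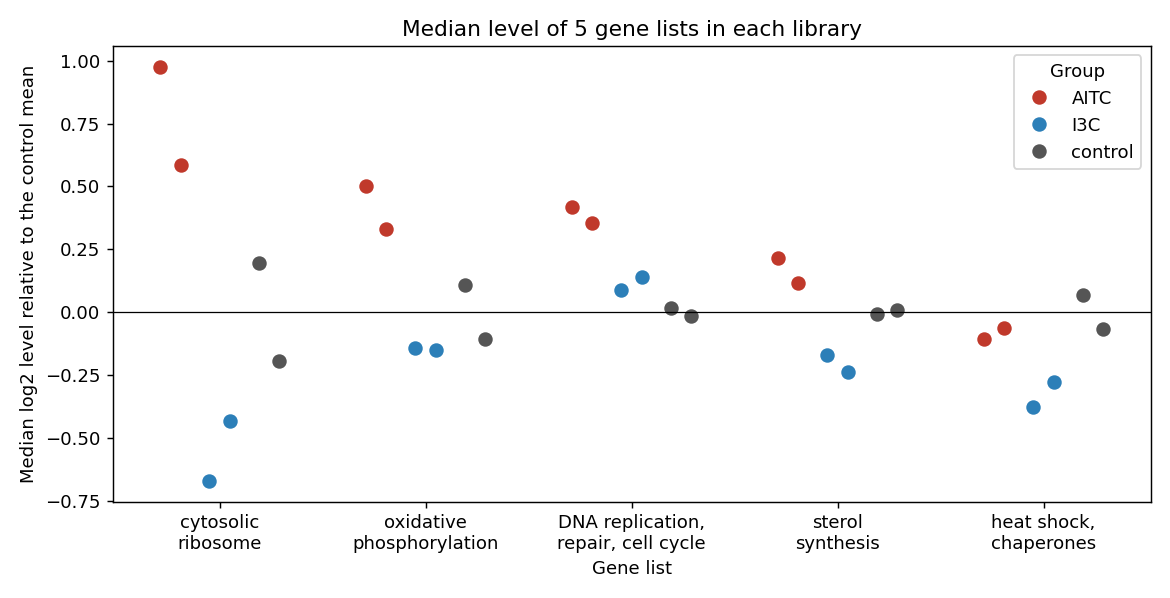
Median log2 level of 5 gene lists in each library relative to the control mean, where points are libraries. The ribosomal protein list stands at 0.97 and 0.58 in the AITC libraries and at -0.67 and -0.43 in the I3C libraries.

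Of 20 locus tags with a published role in pathogenicity or isothiocyanate hydrolysis, 11 rows of 10 tags were tested. SS1G_12040 was called in both comparisons with AITC. Adjusted over the list alone, SS1G_02068 was also higher with AITC than in control (log2 1.64 ± 0.43, edgeR list-alone adjusted p = 0.0332) and than with I3C (1.93 ± 0.44, 0.0153; 2.59 without I3C 2), and SS1G_07836 was higher than with I3C (1.69 ± 0.40, 0.0154). That makes 5 calls over the 3 comparisons, 2 without AITC 2 and 15 without I3C 2. For I3C against control the smallest list-alone adjusted p was 0.168, for SS1G_10796. A second row carrying the tag SS1G_12040 lay near the floor, under 1 CPM in each library, and was not called.

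Across the 12295 tested rows, the log2 changes with AITC and with I3C against the same controls had r = 0.66, a covariance of 0.657 and the same sign in 63.3% of rows. Genes are not independent replicates. In 20 simulations of unchanged groups against shared controls, the mean r was 0.49 (0.46 to 0.51), the covariance 0.123 and the share of the same sign 66.3% (65.6 to 67.3), so the observed share lay below the simulated range. The simulations drew each row on its own, so their ranges leave out variation that rows share. A value outside them therefore does not by itself show a response to the compounds. All simulated values are for the 12295 rows and were not redone on fewer rows. Without the rows read almost only in AITC 1, AITC 2 and I3C 2, r was 0.42 and the share 62.9%. Both lay below the simulated ranges, and the covariance, 0.246, above them. The covariance differed from the simulated mean by 0.123, and by 0.534 with those rows in. With AITC set against control 1 and I3C against control 2, r was 0.47, and 0.16 without those rows, where simulated groups gave -0.02 to 0.03. With the controls exchanged it was 0.42 and 0.12, against -0.02 to 0.03. On the shared controls r was 0.19 without I3C 2 and 0.46 without AITC 2. No row was called in both edgeR comparisons, which had 355 and 1 calls, so that at most 1 could be shared. Some fits with 1 library left out did call rows in both comparisons. Of 9077 rows with an adjusted p in both DESeq2 comparisons, 717 were higher with AITC and 80 with I3C, and 693 and 237 lower. Of these, 16 were higher and 146 lower in both. Independent lists of these sizes would share 6.32 and 18.1, a value that leaves out the shared controls. The simulated groups, which leave out any effect and any variation that rows share, had a mean of 10.7 and 10.2 calls. They shared at most 4 and 2.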

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

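The tests on scaffold rows, single-locus rows, thinned libraries, split controls and rows read almost only in AITC 1, AITC 2 and I3C 2 were chosen after the result was seen. The cause of the changes below was not tested. For AITC against control (355), the count was 1410 with DESeq2, 883 with no filter, 98 with the replicate block, 687 with the 4 compared libraries alone and 224 over scaffold rows alone, and ranged from 0 to 806 when a library was left out. For I3C against control (1) it was 2 with library size alone, 319 with DESeq2, 137 with no filter, 0 with the replicate block, 0 with the 4 compared libraries alone, 4 over scaffold rows, 3 without the rows read almost only in AITC 1, AITC 2 and I3C 2, and 0 to 225 when a library was left out. For AITC against I3C (345) it was 206 with library size alone, 1164 with DESeq2, 813 with no filter, 0 with the replicate block, 539 with the 4 compared libraries alone, and 0 to 372 when a library was left out. The list-alone calls of published genes (5) were 8 with DESeq2, 8 with the 4 compared libraries alone, 3 over single-locus rows and 2 to 15 when a library was left out. Called lists (23) were 0 with an estimated correlation and 2 with fry. The correlation of the AITC and I3C changes (0.66) was 0.47 with AITC against control 1 and I3C against control 2, 0.42 with the controls exchanged, 0.42 without the rows read almost only in AITC 1, AITC 2 and I3C 2, and 0.19 to 0.75 when a library was left out. The replicate block uses the number in the labels, which do not say that it marks a batch. Same-numbered libraries deviated with r of 0.18 for AITC and control, -0.23 for I3C and control and -0.02 for AITC and I3C. With 2 libraries per group this cannot show whether the number pairs the libraries. Of 49 named gene results that passed, 49 kept their call with RLE factors, 49 with DESeq2 and 46 with limma-voom. After thinning 45 kept it, with library size alone 40 and with the replicate block 14. With the block, tcmN against control was among those that lost their call. All 48 that involve AITC lost it without AITC 1 and without AITC 2. None changed direction. With 2 libraries per group and the spread seen, 2-fold changes were mostly missed in simulation.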

Other observations

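The tests on rows read almost only in AITC 1, AITC 2 and I3C 2 and on ribosomal protein genes were chosen after the result was seen, and those on neighbouring rows before. Several rows had their highest group mean with I3C, among them tcmN, NECHADRAFT_80653, aps1 and NRPS4. From this longer set 3 more are given here, chosen after their values were seen. They are leu-1 (220.7 ± 18.9 CPM against 57.0 ± 1.01 in control and 96.8 ± 0.442 with AITC), leu2 (515.3 ± 16.6 against 158.2 ± 45.2 and 143.2 ± 27.6) and kmo (48.6 ± 5.25 against 14.9 ± 1.82 and 15.6 ± 2.30). These 3 were called against AITC in edgeR, and none of them against control.

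The table held 349 rows read almost only in AITC 1, AITC 2 and I3C 2, against at most 34 for any other set of 3 libraries. Only 1.15% of them lie on scaffolds, against 60.8% of all rows, which is consistent with RNA from another organism in these 3 libraries. In 356 contig rows chosen on AITC and control alone, I3C 1 held 1.51% of the reads expected from I3C 2. These values argue against a response shared by both I3C libraries. The lack of reads in I3C 1 had been seen before the choice, so this is not an independent test. A response to AITC was not tested by it, since the rows were chosen for reads in AITC and almost none in control. Depth does not account for the low count in I3C 1, where 3575 reads were expected. Which organism, and whether it entered in culture or at the bench, was not tested.

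Ribosomal protein genes had a median log2 difference of 1.39 between AITC and I3C, with a camera adjusted p of 0.884 with an estimated correlation. The median was 1.26 without AITC 1, 1.59 without AITC 2, 1.11 without I3C 1 and 1.60 without I3C 2. The median was 1.34 over scaffold rows alone, so contigs of another organism are not the whole cause. It was 1.08 with library size alone, against composition scaling. With every library thinned to 1 total it was 1.36, over 87 rows. Changes are already scaled by library size, so thinning could hardly have moved the median and does not test depth as a cause. A response to either compound stays open and was not tested.

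Called rows of AITC against control were tested for lying near another called row of the same direction. Of 138 called single-locus scaffold rows, 21 had such a neighbour 2000 to 20000 bp away, against a mean of 11.9 over 10000 permutations (permutation p = 0.0333, 0.133 adjusted over 4 such tests), so random placement cannot be told apart at this count. With neighbours under 5000 bp not counted there were 15 against 10.02 (permutation p = 0.135), so rows that are pieces of 1 transcript may contribute. For AITC against I3C there were 9 against 12.9 (permutation p = 0.799), and 9 against 10.8 with neighbours under 5000 bp not counted (permutation p = 0.661).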
